A study of Mus musculus with 12 samples.

How the data were processed

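RNA-seq libraries came from mouse OT-I CD8+ T cells given 1 of 4 retroviruses, in 3 libraries each, 12 in all. Per the labels' protocols, sorted cells were lysed in TRIzol and libraries were made with a stranded TruSeq mRNA kit. Each library was deposited by the authors as a table of FPKM, a count of fragments scaled by transcript length and library total, for the same 24346 gene symbols. Per the submitters' processing notes, TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 were used with the mm10 genome build. The role of each tool, the gene annotation, the alignment settings, the strand setting of the counting and any normalization between libraries are not given in the sources used here. The FPKM values deposited by the authors therefore hold whatever scaling those tools applied, and reads from overlapping or antisense genes, from near-identical gene copies and from the retroviral insert were not separated here.

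FPKM values carry no read counts, so the total depth of each library is unknown and no counting intervals were computed. Low values were checked for steps of single fragments: among genes under 0.2 FPKM in Mock replicate 1 and under 0.3 FPKM in the other library, ratios were placed in bins of 0.01 on the log2 scale. Between 25.0% and 30.5% of 474 to 763 such genes lay within 0.02 of the commonest ratio, which gave relative fragment numbers of 0.81 to 1.201 times that of Mock replicate 1. Because most values did not follow these steps, whole fragments were not recovered and no count test was used. No pair of libraries held identical values. The small RNA genes Mir142b and Mir703 were listed at 0 in some libraries while their median was above 20 FPKM, so an exact 0 may be a failed estimate and is given here as listed at 0.

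Values were analysed as log2(FPKM + 1), with a pseudocount of 1. A fold change on this scale understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 10890 in all, and 8496 gene symbols were listed at 0 in every library. A linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend, so all 6 comparisons shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were counted as higher or lower. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical. Transduced genes were also compared with exact two-sided permutation tests, for which 3 libraries against 3 cannot give a p under 0.1. Other tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

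Gene lists of T cell programs, metabolism, stress responses, RNA quality and markers of other cell types were fixed before the data were examined, as were the model, the filter, the pseudocount, the rule for named genes and most of the alternative settings. The 33 lists held 647 genes, of which 521 were tested, and 28 lists had at least 5 tested members. These 28 were tested with camera in limma, which sets the members of a list against all other genes with a preset correlation of 0.01 between members, adjusted over the 28 lists. The same test with a correlation estimated from the data, and the rotation test fry, which asks whether members move one way on balance, were run as alternatives. Members of a list were counted after adjustment over all genes and after adjustment over the list alone. In comparisons with Mock, the named genes were Batf, Batf2 and Batf3, then the 10 highest and the 10 lowest fold changes among genes past the threshold. These needed all 3 libraries of the group above (or below) all 3 Mock libraries and a mean of at least 5 FPKM in the higher group. Symbols made of Gm or LOC and digits, or ending in Rik or -ps, were left out, as were entries that name several genes. Up to 4 members of each list with the smallest adjusted p were added. Between family members the numbers were 5, 5 and 2. The text may leave out genes from the end of each order, may give a gene named in one comparison its values in others, and uses the entry with the highest mean where a symbol has several.

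The labels give the groups the same replicate numbers without saying what a number stands for. Deviations from the group means were correlated across genes, and numbers were taken to pair 2 groups where all 3 correlations were above 0.1. This held for Mock and Batf (0.706, 0.229 and 0.541 for replicates 1, 2 and 3), Mock and Batf3 (0.699, 0.227 and 0.496) and Batf and Batf2 (0.432, 0.229 and 0.315). Replicate 2 gave 0.031 for Mock and Batf2, 0.076 for Batf and Batf3 and 0.004 for Batf2 and Batf3, which were not treated as paired. In the same order, replicates 1 and 3 gave 0.565 and 0.26, 0.593 and 0.397, and 0.524 and 0.165. Numbers that pair Mock with Batf and with Batf3 would also pair Batf with Batf3, so this rule does not show that pairing is absent. The main fit held no block, and fits with the replicate number as a block were computed for all comparisons. The other alternatives changed the pseudocount, the filter, the normalization, the set of libraries, the variance model and the weights of libraries, or left out 1 library. Removal of a trend on transcript length was added after the data were seen, as were fits without the library that stood apart for comparisons without its group, for lists and for overlaps. Transcript lengths and positions came from GENCODE release M21 for mm10, which gave a length for 10485 (96.3%) of the tested genes. The steps were tested on simulated data with the gene means and spread of the 12 libraries. Of 10890 genes, 200 were changed in the Batf libraries in each of 10 simulations, and Batf was compared with Mock. The steps recovered 49.1% of 2-fold and 95.6% of 4-fold changes, with 4.6% false calls and the right sign in 100% of recovered genes. Lists of 20 genes shifted by 0.5 on the log2 scale were recovered in 100% of 50 simulations, and 4% of unshifted lists passed, by camera p before adjustment. Genes were drawn independently, with no correlation between members and no shared replicate effect. These rates therefore do not cover lists whose members move together. Because comparisons with Mock share control libraries, unchanged groups were simulated against shared controls 100 times to give the overlap and correlation that arise with no effect. Libraries were drawn independently of one another there, so no replicate effect was shared between groups.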

Results

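Transcript levels were measured by RNA-seq in mouse CD8+ T cells that carry the OT-I transgenic receptor, which recognizes a peptide of chicken ovalbumin. Naive cells from the spleen were stimulated with antibodies to CD3 and CD28 in the presence of interleukin 2. On day 1 they received an empty retrovirus (Mock) or one that encoded Batf, Batf2 or Batf3. From day 4 they were kept for 4 days in interleukin 2 without antibody, and cells with the GFP marker were sorted on day 8. Batf, Batf2 and Batf3 are basic leucine zipper transcription factors of the AP-1 superfamily, and the study concerned the distinct functions of these family members. Each group had 3 libraries, and all values below are mean FPKM ± SD with n = 3 per group unless stated otherwise. Log2 fold changes, where an error is given, are ± SE. Between 10189 and 10591 genes per library had at least 1 FPKM.

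In 11 of the 12 libraries the FPKM values summed to between 579078 and 671072, while those of Batf2 replicate 3 summed to 1435117. The 50 most abundant transcripts took 41.8% of the total in this library, against 25.8% to 30.34% in the others. Levels in Batf2 replicate 3 also fell with transcript length: the median deviation from the mean of the 12 libraries was 0.37 on the log2 scale for genes under 1000 nt and −0.84 for those of 4000 nt or more. Its correlation with the other Batf2 libraries over the tested genes was 0.907 and 0.929, whereas other pairs of replicates ranged from 0.939 to 0.991. Some markers of other cell types were higher in this library than in the other Batf2 libraries. Cd79b, part of the B cell receptor, stood at 28.8 FPKM against at most 10.6 in the other Batf2 libraries, and the globin gene Hba-a1 at 18.6 against at most 4.61. Hba-a1 was also higher in Batf2 than in Batf and Batf3 cells without this library (1.80 and 2.08, adjusted p = 0.0104 and 0.0079). Both genes were chosen after their values were seen. Genes that mark no other cell type were higher in this library too. The mean log2 level of oxidative phosphorylation genes was 8.49, against 6.99 and 7.21 in Batf2 replicates 1 and 2.

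**Figure D1:**
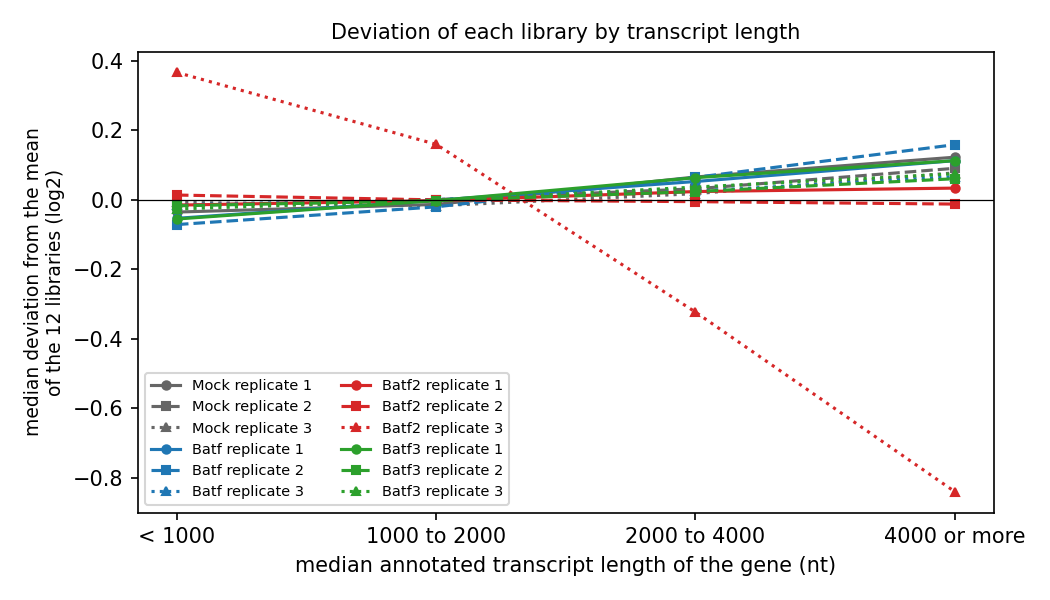
Median deviation of each library from the mean of the 12 libraries (y axis, log2) for tested genes in 4 classes of median annotated transcript length (x axis, nt), with 1 line per library, colour for the group and line style for the replicate. The line of Batf2 replicate 3 ran from 0.37 in the shortest class to −0.84 in the longest, and the other 11 lines lay between −0.071 and 0.159.

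The transduced genes were examined first, as a check of the labels. Batf (chromosome 12, 85686669 to 85709087, mm10) reached 577 ± 187 FPKM in Batf cells against 58.7 ± 10.8 in Mock, a log2 fold change of 3.24 ± 0.31 (SE, limma adjusted p = 0.000169). Batf2 (chromosome 19, 6140983 to 6172476) was listed at 0 in all 9 libraries of the other groups and reached 391.6, 422.6 and 368.7 FPKM in the Batf2 libraries. Batf3 (chromosome 1, 191097847 to 191108945) rose from 0.16 ± 0.139 in Mock to 586 ± 192 in Batf3 cells, by 8.93 ± 0.54 (adjusted p = 1.16e-05). Each gene is protein-coding and lies on the plus strand. FPKM values do not separate the retroviral insert from the endogenous gene. The Batf3 transcript was also above Mock in cells given another family member, at 9.26 ± 2.89 FPKM in Batf cells (log2 fold change 3.11, adjusted p = 0.0064) and 19.4 ± 20.5 in Batf2 cells (3.68, adjusted p = 0.0016). The 3 Batf2 libraries held 7.18, 7.89 and 43.1 FPKM of Batf3, the highest in replicate 3. Batf was not past the threshold in Batf2 cells (64.4 ± 31.4 FPKM, adjusted p = 0.946) or in Batf3 cells (38.4 ± 0.718, adjusted p = 0.756). All 3 Batf3 libraries (37.6 to 38.9 FPKM) nevertheless lay below all 3 Mock libraries (48.2 to 69.7), with an exact two-sided permutation p of 0.1. In exact two-sided permutation tests of each transduced gene against Mock, p was 0.1, the smallest that 3 libraries against 3 allow.

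**Figure D2:**
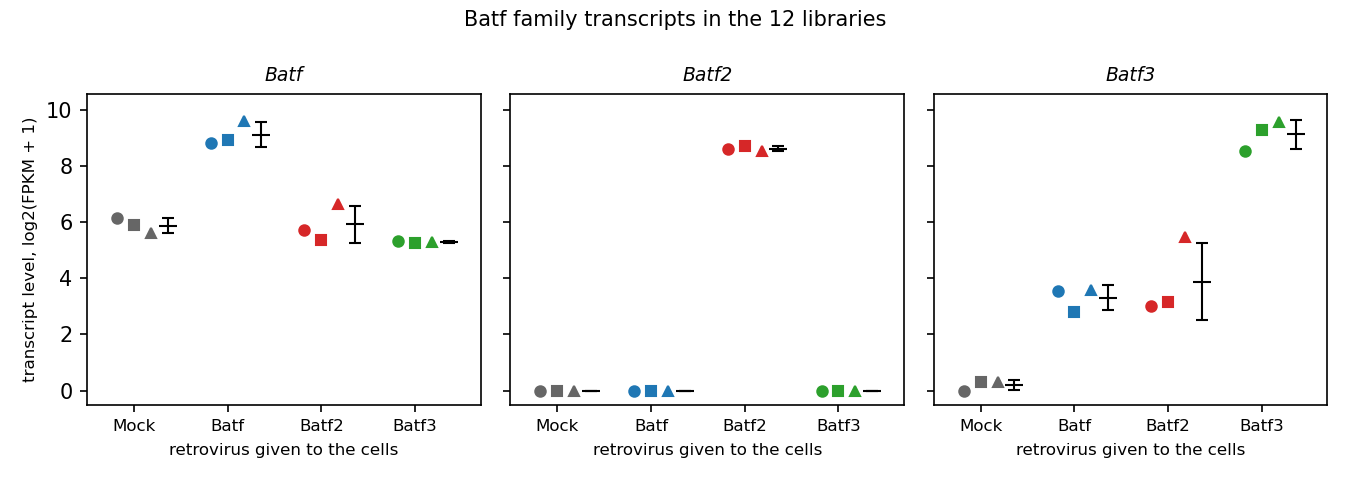
Levels of the 3 Batf family transcripts on the log2(FPKM + 1) scale (y axis) in cells given each retrovirus (x axis); points are libraries (circle, square and triangle for replicates 1, 2 and 3) and black bars give the mean ± SD of 3 libraries. Each transcript was highest in the group given its own retrovirus, and the 3 Mock libraries lay below all Batf and Batf2 libraries for Batf3.

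The comparison of Batf with Mock asked which transcripts differed when Batf was supplied. Itgae, which encodes the CD103 chain of the integrin that binds E-cadherin, rose from 0.964 ± 0.458 to 88.5 ± 18.4 FPKM, a log2 fold change of 5.52 ± 0.33 (SE, adjusted p = 6.12e-06). Gzmc, which encodes the serine protease granzyme C, rose from 44.7 ± 12.5 to 868 ± 78.9 FPKM (4.28 ± 0.24, adjusted p = 6.12e-06). The chemokine receptor gene Ccr1 rose by 3.89, Tnfrsf8 (CD30, of the TNF receptor family) by 3.66, and Il1r2, which encodes the decoy receptor for interleukin 1, by 3.58. Il10, an anti-inflammatory cytokine gene, rose from 3.19 ± 2.46 to 38.3 ± 18.3 FPKM (3.38 ± 0.58, adjusted p = 0.0061). Among transcripts that fell, Tgm2 (transglutaminase 2) went from 34.7 ± 20.3 to 0.159 ± 0.0096 FPKM (−4.71 ± 0.46, adjusted p = 0.000209). Cd300lf, an inhibitory receptor gene, changed by −2.78, the protease inhibitor gene Serpinb1a by −2.63, and Upp1 (uridine phosphorylase) by −2.55. The lowest value was that of Rps27rt (−6.36 ± 1.55, adjusted p = 0.0473), which is near-identical to the ribosomal protein gene Rps27, so reads may be split between them. Its call ended under several alternatives (adjusted p 0.0536 to 0.152), among them the replicate block (0.0571) and leaving out any 1 Mock library or Batf replicate 1 or 2.

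The cytokine and chemokine list rose against other genes (adjusted p = 8.63e-06, and 0.0196 with an estimated correlation): 6 of 19 tested members were higher and 0 lower, or 8 and 1 adjusted over the list alone. Csf1, the macrophage colony-stimulating factor gene, rose from 1.06 ± 0.257 to 10.9 ± 1.08 FPKM (2.54), the chemokine gene Ccl4 by 2.17 and the cytokine gene Il24 by 2.31. The effector differentiation list also rose (adjusted p = 3.32e-05, and 0.0326 with an estimated correlation), with 1 of 21 members higher and 7 adjusted over the list alone. That member was Tbx21, which encodes the transcription factor T-bet, at 26.9 ± 0.671 FPKM against 9.58 ± 1.17 (1.40, adjusted p = 0.000353). Tissue residency genes rose (adjusted p = 0.000348, and 0.0473 with an estimated correlation; 3 of 11 higher, 5 adjusted over the list alone), Itgae with the highest value. Targets of p53 rose (adjusted p = 1.55e-06, and 0.0326 with an estimated correlation; 3 of 15 higher, 6 adjusted over the list alone). Their members Plk2, Tnfrsf10b and Mdm2 were higher by 1.37, 0.70 and 0.66. Leaving out any 1 of the 6 libraries ended the calls of Tnfrsf10b and Mdm2 (adjusted p 0.0547 to 0.133), and that of Plk2 ended without Mock replicate 2 or Batf replicate 1 or 3 (0.0842 to 0.0896).

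Inhibitory receptor and exhaustion genes moved both ways: 6 of 17 were higher and 2 lower, or 7 and 2 adjusted over the list alone (list median −0.01, mean 0.22, test upward with adjusted p = 0.112). Pdcd1, which encodes PD-1, rose from 6.74 ± 1.72 to 25.9 ± 1.77 FPKM (1.82) and Klrc1 by 1.13, while Btla fell (−1.78) and Tox, a factor linked to exhaustion, fell (−1.54). Cytotoxic molecules also moved both ways (3 of 20 higher, 2 lower; 3 and 4 adjusted over the list alone; list adjusted p = 0.732), with Gzmc and Gzmf higher (2.37 for Gzmf, whose call ended without Mock replicate 2 or 3 or Batf replicate 1 or 2, at 0.0579 to 0.0923) and the granzyme M gene Gzmm lower (−1.68). Gzma, which encodes granzyme A, stood at 8918 ± 1125 FPKM against 3504 ± 1116 (1.39, adjusted p = 0.0187). Its call ended under quantile normalization (adjusted p = 0.0619), with no filter (0.0891) and without Mock replicate 1 or 3 or any 1 Batf library (0.0519 to 0.0899). Of cytokine receptors 4 of 23 were higher and 1 lower (4 and 2 adjusted over the list alone; list adjusted p = 0.107), among them Il7r, the interleukin 7 receptor gene, which rose by 3.27. Of chemokine receptors and adhesion genes 2 of 20 were higher and 1 lower (4 and 1 adjusted over the list alone; list adjusted p = 0.329). Ccr4 rose by 2.42. Of naive and memory genes 1 of 25 was higher (Il7r) and 2 were lower, among them the kinase gene Txk (−1.43), with 2 and 2 adjusted over the list alone. Costimulatory receptors gave 2 higher and 1 lower of 16 (3 and 2 adjusted over the list alone; list adjusted p = 0.457), with Icos higher by 1.66 and Cd6 lower (−1.36).

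Glycolysis genes fell as a list (median log2 fold change −0.80, adjusted p = 7.09e-08, but 0.291 with an estimated correlation), with 1 of 21 members lower over all genes and 5 adjusted over the list alone. Interferon-stimulated genes fell (adjusted p = 0.0018, and 0.207 with an estimated correlation; 1 of 32 lower, 1 adjusted over the list alone), as did MHC class I presentation genes (adjusted p = 0.0077, and 0.5 with an estimated correlation; 0 of 17, 0 adjusted over the list alone). Lineage factors of other T cell subsets rose (adjusted p = 1.50e-05, and 0.0703 with an estimated correlation; 2 of 10 higher, 3 adjusted over the list alone), through Il10 and Maf, a transcription factor gene that rose by 2.68. Of marker lists of other cells, those for NK and innate-like cells (2 of 9 higher), dendritic cells (2 of 7) and CD4 and regulatory T cells (1 of 7) rose with adjusted p of 0.000892, 0.0011 and 0.0027. Adjusted over the list alone these counts were 6 (with 1 lower), 4 and 1, and the list adjusted p were 0.214, 0.0889 and 0.0528 with an estimated correlation. Fcer1g, the Fc receptor common gamma chain gene, rose by 1.14, and Cd74, the MHC class II invariant chain gene, by 2.99. With the replicate block, the naive and memory list (adjusted p = 0.0563 without it) and the cholesterol synthesis list (0.0563) passed as lower, at 0.0299 and 0.0047, but in that fit their adjusted p was 0.5802 and 0.5545 with an estimated correlation. In limma, 377 of 10890 genes passed an adjusted p of 0.05, 297 higher and 80 lower, 285 of them by at least 2-fold. The groups did not overlap for 21.7% of genes, where chance gives 10%. The count was 586 with the replicate block, 763 without Batf2 replicate 3, which shares the estimate of the spread, and 232, 232, 234 and 241 without Mock replicate 2 or Batf replicate 1, 2 or 3.

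**Figure D3:**
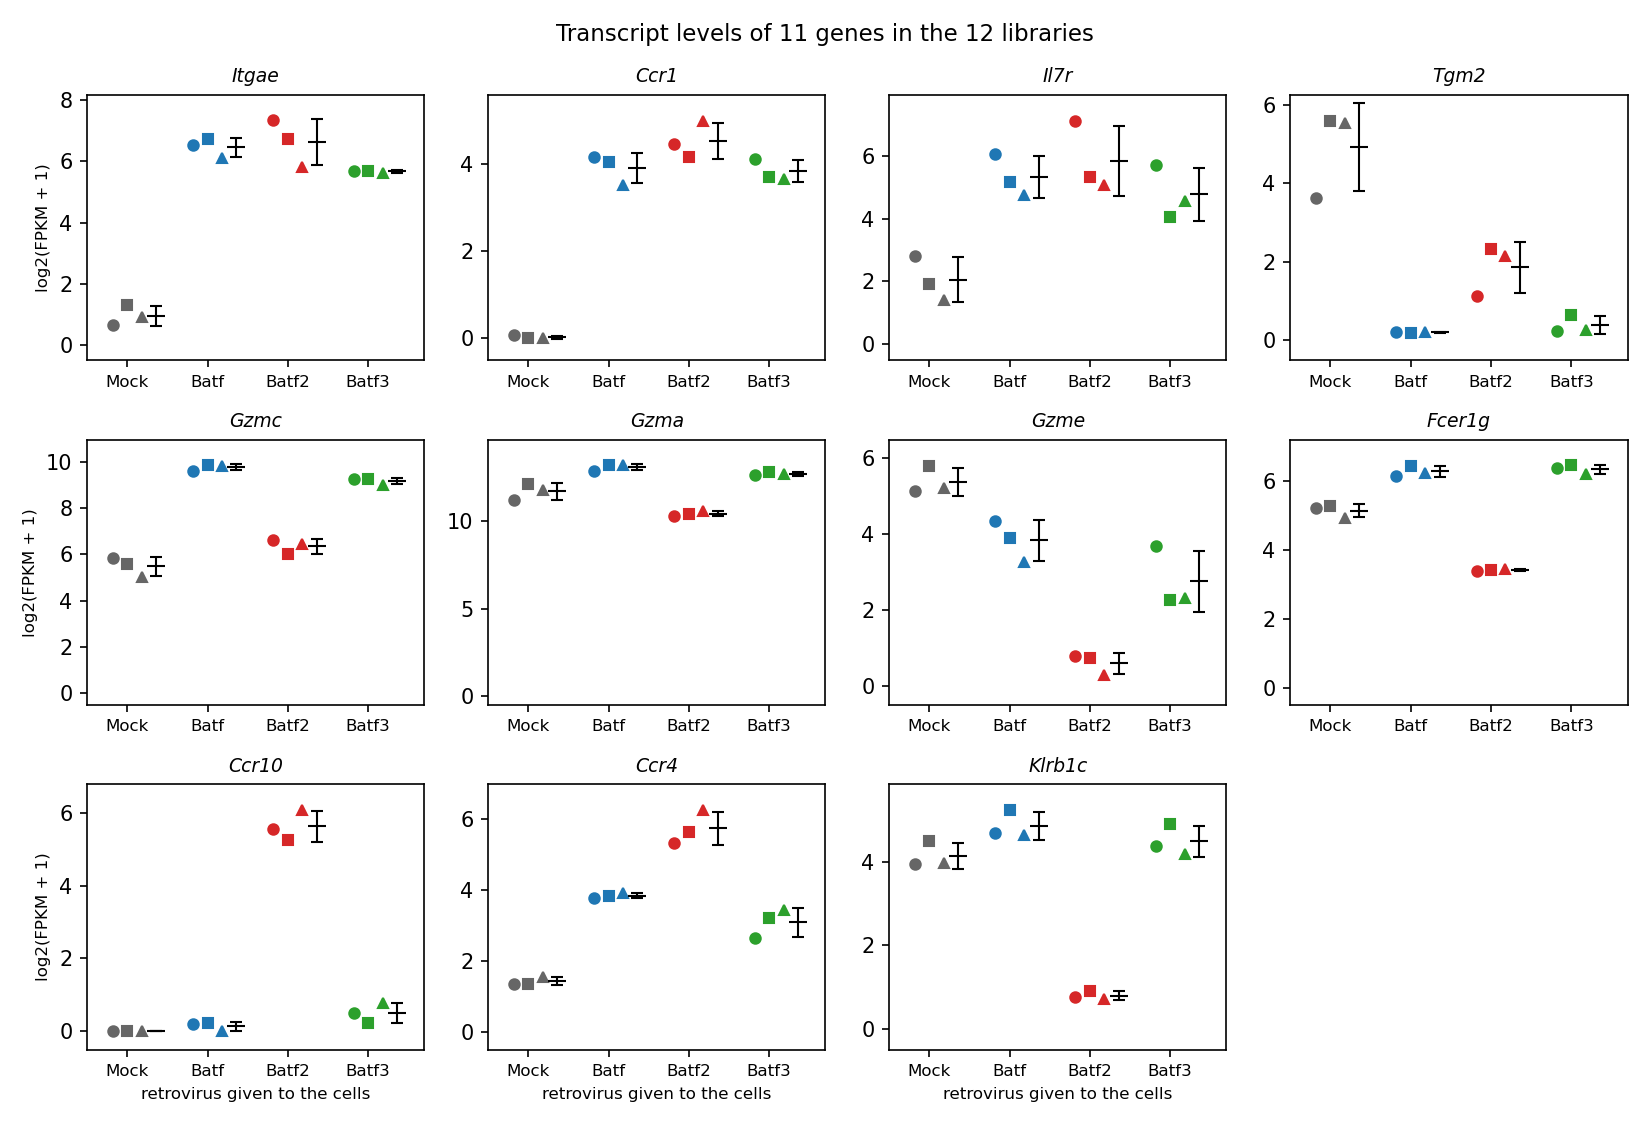
Levels of 11 genes on the log2(FPKM + 1) scale (y axis) in cells given each retrovirus (x axis); points are libraries (circle, square and triangle for replicates 1, 2 and 3) and black bars give the mean ± SD of 3 libraries. Itgae and Ccr1 were above Mock in all 9 libraries given a family member, while Gzmc and Fcer1g separated the Batf and Batf3 libraries from the Batf2 libraries.

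Cells given Batf2 were compared with Mock to find the transcripts that differed with this family member. Itgae rose to 108 ± 52.7 FPKM (5.69 ± 0.33, adjusted p = 2.42e-06). Ccr10, a receptor gene for skin and mucosal chemokines, was listed at 0 in all 3 Mock libraries and stood at 49.7 ± 14.9 FPKM in Batf2 cells (adjusted p = 5.58e-08). Igfbp4, which encodes a binding protein of insulin-like growth factors, rose from 6.62 ± 1.97 to 281 ± 137 FPKM (5.12), and the gut homing receptor gene Gpr15 by 4.92. Ccr1 and Ccr4 rose by 4.51 and 4.31. The granzyme genes Gzme and Gzmd fell from 41.3 ± 11.4 and 66.3 ± 21.1 to 0.532 ± 0.277 and 1.60 ± 0.541 FPKM (−4.77 and −4.67). Gzmg changed by −3.93. Gzmd, Gzme, Gzmf and Gzmg are close copies of one another, so how reads were split among them is uncertain. Klrb1c, which encodes the NK cell marker NK1.1, fell from 17.0 ± 4.03 to 0.739 ± 0.125 FPKM (−3.35 ± 0.24, adjusted p = 1.58e-05), and Tgm2 fell to 2.86 ± 1.49 (−3.06).

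Cytotoxic molecules fell as a list (adjusted p = 0.000872, but 0.282 with an estimated correlation), with 9 of 20 members lower and 0 higher (9 and 1 adjusted over the list alone). Gzmk (granzyme K) fell from 104 ± 33.6 to 15.3 ± 10.5 FPKM (−2.84), and the granzyme inhibitor gene Serpinb6b changed by −1.88. Chemokine receptors and adhesion genes rose (adjusted p = 0.0044, and 0.282 with an estimated correlation; 5 of 20 higher and 1 lower, 9 and 1 adjusted over the list alone), among them Itgb7, an integrin chain of gut homing, at 502 ± 99.0 FPKM against 139 ± 12.3 (1.83). Tissue residency genes were split: 3 of 11 were higher and 6 lower, the same numbers adjusted over the list alone. Ccr10 and Itgae were higher, and Xcl1 (−2.28) and Cdh1, the E-cadherin gene (−1.91), were lower. The median of this list was −0.96 while its mean was 0.34, and it did not pass (adjusted p = 0.346). Of naive and memory genes 4 of 25 were higher and 1 lower (8 and 2 adjusted over the list alone; list adjusted p = 0.133). Id3, a transcription factor gene of memory cells, rose from 5.82 ± 0.946 to 56.5 ± 40.9 FPKM (2.86), and the surface receptor gene Slamf6 by 2.89, while the kinase gene Txk changed by −1.45.

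Of effector differentiation genes 5 of 21 were higher and 2 lower (8 and 3 adjusted over the list alone; list adjusted p = 0.174), including the calcium-binding protein gene S100a4 (3.45), Tbx21 (1.08) and Itgam, which encodes CD11b (2.74). S100a4 stood at 15575 ± 14614 FPKM against 1096 ± 210 in Mock, a spread between the Batf2 libraries near the size of their mean. When only these 2 groups were fitted, the calls of S100a4 and Tbx21 ended (0.0527 and 0.0691). Inhibitory receptor and exhaustion genes gave 2 higher and 4 lower of 17 (9 and 5 adjusted over the list alone; list adjusted p = 0.508): Tigit rose by 1.30, while Entpd1 (CD39) and the orphan receptor gene Nr4a3 fell (−1.47 and −1.27). Among cytokines 3 of 19 were higher and 2 lower (4 and 3 adjusted over the list alone; list adjusted p = 0.417), with Tnfsf11 (RANKL) lower (−1.30). Costimulatory receptors gave 3 higher and 2 lower of 16 (5 and 3 adjusted over the list alone; list adjusted p = 0.133), with Icos higher by 1.46 and Tnfrsf8 by 3.14. Interferon-stimulated genes fell (adjusted p = 0.0075, and 0.363 with an estimated correlation; 1 of 32 higher and 3 lower, 1 and 8 adjusted over the list alone), although Ifi204, a DNA sensor gene, rose by 2.73. The list of immediate early and heat shock genes fell (adjusted p = 0.005, and 0.363 with an estimated correlation; 3 of 17 lower, 5 adjusted over the list alone). Egr1, which is induced by receptor signals, stood at 18.8 ± 17.2 FPKM against 114 ± 19.3 (−3.01, adjusted p = 0.0121), and its call ended when only the libraries of these 2 groups were fitted (0.0983).

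Cytosolic ribosomal protein genes rose as a list (median 0.66, adjusted p = 7.03e-05, and 0.634 with an estimated correlation), as did oxidative phosphorylation genes (0.54, 0.000521, and 0.634), cell cycle genes (0.45, 0.0104, and 0.734) and fatty acid oxidation genes (0.28, 0.0216, and 0.634). Without Batf2 replicate 3 none of these lists passed, with adjusted p of 0.129, 0.51, 0.077 and 0.743. Under quantile normalization the ribosomal and fatty acid oxidation lists did not pass either (0.442 and 0.0723), nor did fatty acid oxidation with the length trend removed (0.077). Members past the threshold numbered 1 of 39, 0 of 32, 1 of 39 and 0 of 17, the same adjusted over the list alone. Dendritic cell markers rose (adjusted p = 0.0095, and 0.282 with an estimated correlation; 3 of 7, 3 adjusted over the list alone), as did CD4 and regulatory T cell markers (0.000511, and 0.0782 with an estimated correlation; 3 of 7, 7 adjusted over the list alone). Cd74 rose to 17.3 ± 13.1 FPKM (3.24) and Cd79b to 15.8 ± 11.4 (2.75), each highest in replicate 3. The lists for p53 targets (adjusted p = 0.0091, 0 of 15 higher, 6 adjusted over the list alone) and lineage factors of other subsets (0.0095, 4 of 10 higher, 6 higher and 2 lower adjusted over the list alone) rose, with adjusted p = 0.282 and 0.363 with an estimated correlation. Of NK markers 1 of 9 was higher and 3 were lower (1 and 4 adjusted over the list alone; list adjusted p = 0.128), with Klri2 higher (2.72) and Fcer1g down from 34.2 ± 4.33 to 9.64 ± 0.193 FPKM (−1.72). In limma, 689 genes passed, 455 higher and 234 lower, 480 of them by at least 2-fold. The groups did not overlap for 20.8% of genes, where chance gives 10%. When only the 6 libraries of these groups were fitted, 199 genes passed, all among the 689, and without Mock replicate 2 the count was 382. Without Batf2 replicate 3, 725 genes passed, and 560 of the 689 were among them.

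**Figure D4:**
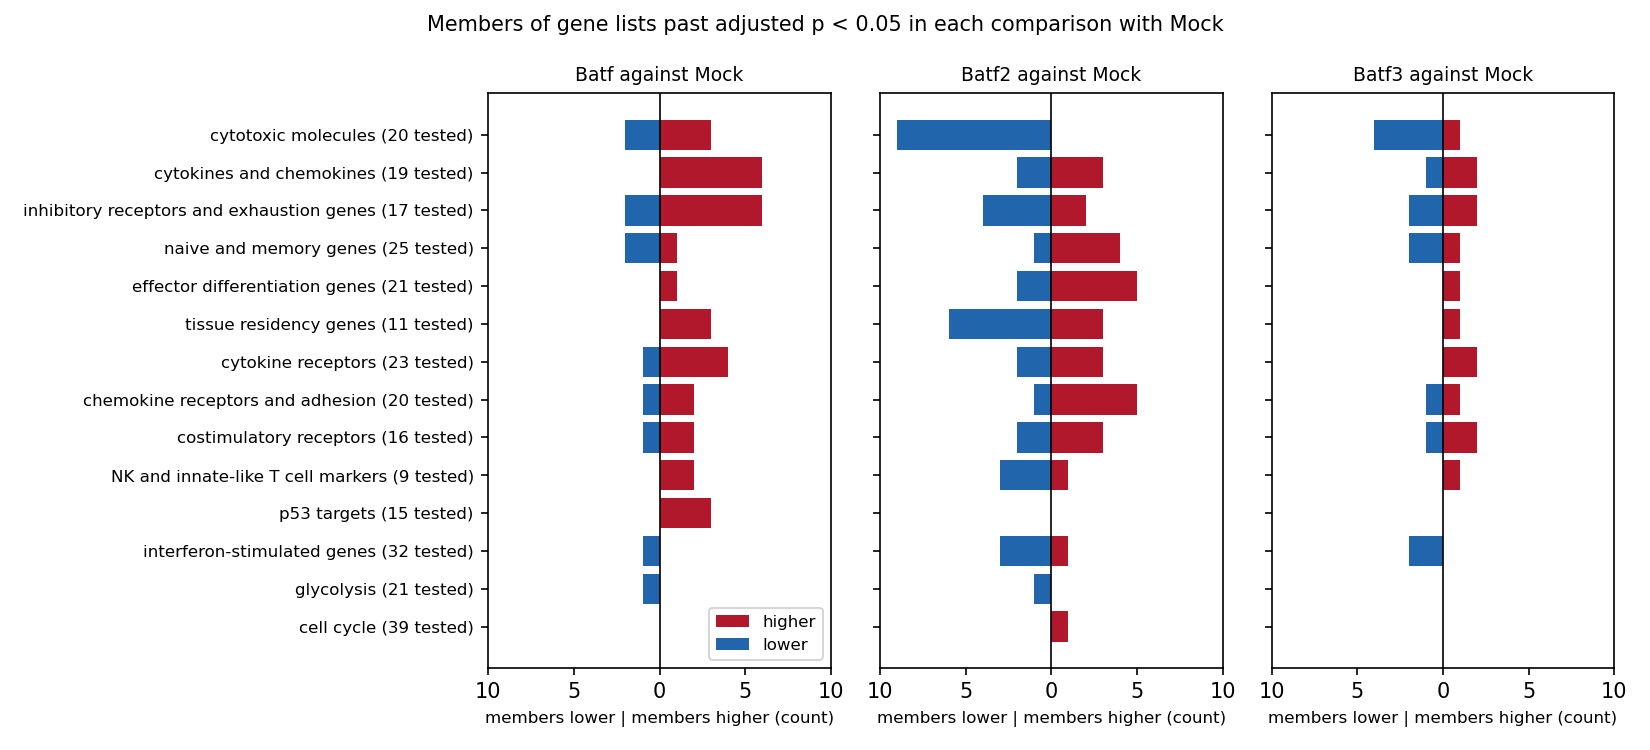
Numbers of members (x axis, count) of 14 gene lists past an adjusted p of 0.05 over all genes in each comparison with Mock, with bars to the right for members higher and to the left for members lower than in Mock. Of 20 cytotoxic molecules, 9 were lower in Batf2 cells and 4 in Batf3 cells, and of 19 cytokine and chemokine genes 6 were higher in Batf cells.

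Cells given Batf3 were compared with Mock in the same way. Itgae rose to 50.1 ± 1.37 FPKM (4.73 ± 0.33, adjusted p = 1.86e-05), Ccr1 by 3.81, and Gzmc to 573 ± 55.1 FPKM (3.68 ± 0.24, adjusted p = 1.17e-05). The microRNA gene Mir703 had the lowest value: it stood at 58.1 ± 19.2 FPKM in Mock and was listed at 0 in all 3 Batf3 libraries. Its zeros are uncertain, and its call ended without any 1 of the 6 libraries (adjusted p 0.0536 to 0.107). Tgm2 fell to 0.321 ± 0.22 FPKM (−4.53). Gzmd, Gzmg and Gzme changed by −2.72, −2.67 and −2.62, with the uncertainty of these gene copies given above. The call of Gzmg ended without Mock replicate 1 or 2 or Batf3 replicate 2 or 3 (0.0797 to 0.112). Spp1, which encodes the cytokine-like protein osteopontin, fell from 136 ± 22.6 to 25.3 ± 7.83 FPKM (−2.41).

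The cytokine and chemokine list rose (adjusted p = 0.0013, and 0.0302 with an estimated correlation), with 2 of 19 members higher and 1 lower, or 6 and 1 adjusted over the list alone. Csf1 rose to 8.99 ± 0.467 FPKM (2.28) and Ccl4 by 1.67, while Tnfsf11 fell (−1.60). Effector differentiation genes rose (adjusted p = 8.95e-06, and 0.0302 with an estimated correlation; 1 of 21 higher, 4 adjusted over the list alone), with Tbx21 at 32.4 ± 2.31 FPKM (1.66, adjusted p = 0.000239). Lineage factors of other subsets (1 of 10 higher, 8 adjusted over the list alone), p53 targets (0 of 15, 6 adjusted over the list alone) and CD4 and regulatory T cell markers (0 of 7, 5 adjusted over the list alone) rose with adjusted p of 6.28e-08, 6.46e-06 and 0.000165. With an estimated correlation each of these 3 lists had an adjusted p of 0.0302. Interferon-stimulated genes fell (adjusted p = 1.15e-07, and 0.0311 with an estimated correlation), with 2 of 32 members lower and 2 adjusted over the list alone.

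Glycolysis genes (adjusted p = 6.28e-08, 0 of 21 lower, 4 adjusted over the list alone) and MHC class I presentation genes (0.0013, 0 of 17, 0 adjusted over the list alone) fell as lists, and NK markers (0.0011, 1 of 9 higher, 5 adjusted over the list alone) rose. Their adjusted p were 0.347, 0.367 and 0.253 with an estimated correlation. The NK marker that passed was Fcer1g, at 79.8 ± 7.30 FPKM (1.20). Tissue residency genes rose (adjusted p = 0.0368, and 0.212 with an estimated correlation; 1 of 11 higher, 3 higher and 1 lower adjusted over the list alone), but not without Batf2 replicate 3 (0.0636) or under quantile normalization (0.0504). Of cytotoxic molecules 1 of 20 was higher and 4 were lower (3 and 5 adjusted over the list alone; list median 0.02, mean −0.19, adjusted p = 0.459). Pdcd1 rose to 26.3 ± 4.46 FPKM (1.83) and Btla fell (−1.48), among 2 higher and 2 lower of 17 inhibitory receptor and exhaustion genes (5 and 3 adjusted over the list alone; list adjusted p = 0.285). Ccr4 rose by 1.67 and Txk fell (−1.25). Il7r was higher by 2.71 (adjusted p = 0.0405), but not without Mock replicate 2 or 3 or any 1 Batf3 library (0.0593 to 0.1678), with no filter (0.072), with a filter at 5 FPKM (0.0514) or when only these 2 groups were fitted (0.0508). With the replicate block, cholesterol synthesis genes passed as lower (adjusted p = 0.0283 against 0.162 without it), but in that fit the adjusted p was 0.6332 with an estimated correlation. In limma, 222 genes passed, 166 higher and 56 lower, 171 of them by at least 2-fold, and the groups did not overlap for 19.4% of genes, where chance gives 10%. The count was 362 with the replicate block, 448 without Batf2 replicate 3, and 114, 133, 120, 116 and 108 without Mock replicate 2 or 3 or Batf3 replicate 1, 2 or 3.

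Batf3 and Batf cells were then compared directly. Beyond the transduced genes, Npnt, which encodes the extracellular matrix protein nephronectin, stood at 0.721 ± 0.155 FPKM in Batf3 cells and 6.30 ± 2.01 in Batf cells (−2.05 ± 0.20, adjusted p = 0.000802), and the transcription factor genes Msc and Pparg were lower in Batf3 cells (−1.98 and −1.83). Arl4d, a small GTPase gene, was higher (0.98, adjusted p = 0.0394). With a pseudocount of 0.1, the adjusted p were 0.0567, 0.0729, 0.059 and 0.0729 for Npnt, Msc, Pparg and Arl4d. The call of Msc also ended without Batf replicate 1 or Batf3 replicate 1 or 2 (0.0515 to 0.0578), and that of Arl4d without any 1 of the 6 libraries (0.125 to 0.287), with a filter at 5 FPKM (0.214), under quantile normalization (0.0723) and with only these 2 groups fitted (0.0698). The cytokine and chemokine list was lower in Batf3 cells (adjusted p = 7.39e-06, and 0.0144 with an estimated correlation), with 0 of 19 members past the threshold and 2 adjusted over the list alone. Tnfsf11 and Il24 gave −0.94 and −1.53 (adjusted p = 0.196 and 0.425).

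Tissue residency genes (adjusted p = 0.000554), cytotoxic molecules (0.000738), dendritic cell markers (0.0046), interferon-stimulated genes (0.0144), costimulatory receptors (0.0286) and p53 targets (0.0343) were also lower in Batf3 than in Batf cells as lists, and naive and memory genes (0.0144) were higher. None of these 7 lists had a member past the threshold over all genes, and adjusted over the list alone 2 residency genes, 1 dendritic cell marker and 1 costimulatory receptor passed as lower. With an estimated correlation their adjusted p, in the same order, were 0.0778, 0.185, 0.185, 0.336, 0.185, 0.336 and 0.925. Without Batf2 replicate 3 the costimulatory receptor and p53 lists did not pass (0.0624 for each). In limma, 16 genes passed, 3 higher and 13 lower in Batf3 cells, 15 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 230 of 10890 genes, a smaller share than the 0.05 that no difference would give. A share this small can come from a test that is too strict, so it does not show that Batf3 and Batf cells are alike. The groups did not overlap for 10.4% of genes, where chance gives 10% if libraries share no replicate effect. With the replicate block and without Batf2 replicate 3, 79 genes passed. In the fit without the block, the count was 4 with a pseudocount of 0.1, 41 with no filter, and 6, 9, 6, 7 and 10 without Batf replicate 1 or 2 or Batf3 replicate 1, 2 or 3.

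The comparison of Batf2 with Batf asked where these family members differed. Ccr10 stood at 49.7 ± 14.9 FPKM in Batf2 cells and 0.105 ± 0.0913 in Batf cells (5.48 ± 0.21, adjusted p = 7.45e-08). Gpr15 and Igfbp4 were higher by 3.10 and 2.91. Klrb1c was lower in Batf2 cells, at 0.739 ± 0.125 against 28.5 ± 7.07 FPKM (−4.06), as was Ppp2r2c, which encodes a regulatory subunit of protein phosphatase 2A (−3.45). Gzmc stood at 82.0 ± 17.8 FPKM in Batf2 cells and 868 ± 78.9 in Batf cells (−3.41 ± 0.24, adjusted p = 1.57e-05). Gzma stood at 1388 ± 139 and 8918 ± 1125 FPKM (−2.68 ± 0.29, adjusted p = 0.000399).

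Cytotoxic molecules were lower in Batf2 than in Batf cells (adjusted p = 2.01e-06, and 0.0732 with an estimated correlation; 8 of 20 lower, 10 adjusted over the list alone), as were cytokines and chemokines (0.0018, and 0.0732 with an estimated correlation; 6 of 19, or 9 lower and 1 higher adjusted over the list alone), among them Csf1 (−1.70) and Ccl4 (−2.12). Tissue residency genes were lower (0.002, and 0.12 with an estimated correlation; 6 of 11 lower and 1 higher, 6 and 2 adjusted over the list alone), with Rgs1, a regulator of G protein signalling, at 12.3 ± 0.665 against 57.6 ± 10.2 FPKM (−2.12). NK markers were lower (0.002, and 0.433 with an estimated correlation; 3 of 9 lower and 1 higher, the same adjusted over the list alone), including Fcer1g (−2.85). Naive and memory genes were higher (adjusted p = 0.0024, and 0.611 with an estimated correlation; 7 of 25 higher, or 7 higher and 1 lower adjusted over the list alone), with Nsg2 (1.91) among them. Chemokine receptors and adhesion genes were higher (0.0168, and 0.433 with an estimated correlation; 7 of 20 higher and 1 lower, 9 and 3 adjusted over the list alone), although not under quantile normalization (0.162). Itgb1, an integrin chain gene, was higher by 1.42. Inhibitory receptor and exhaustion genes gave 3 higher and 5 lower of 17 (4 and 7 adjusted over the list alone; list adjusted p = 0.302), with Btla higher (1.80) and Cd244 lower (−2.26). Immediate early and heat shock genes were lower as a list (0.0128, and 0.563 with an estimated correlation; 3 of 17 lower, or 5 lower and 1 higher adjusted over the list alone).

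Lists of growth and metabolism were also higher in Batf2 than in Batf cells. They were cytosolic ribosomal proteins (adjusted p = 2.01e-06, 0 of 39 members higher), oxidative phosphorylation (4.77e-05, 0 of 32), cell cycle (0.002, 0 of 39), glycolysis (0.0128, 1 of 21) and fatty acid oxidation (0.0461, 0 of 17), the same counts adjusted over the list alone. With an estimated correlation the adjusted p was 0.611 for each of the 5. These member counts come from the fit without the replicate block. With it, E2f2 and Cenpa of the cell cycle list passed as higher (limma adjusted p = 0.0281 and 0.0089). Of oxidative phosphorylation genes, Cyc1 passed with it (0.0378) and Ndufv1 did not (0.0799). Without Batf2 replicate 3 the lists of oxidative phosphorylation, glycolysis and fatty acid oxidation did not pass (0.0657, 0.0739 and 0.933), nor did fatty acid oxidation with the replicate block (0.0568). Under quantile normalization the ribosomal, glycolysis and fatty acid oxidation lists did not pass (0.0828, 0.0828 and 0.294), nor did the last with the length trend removed (0.211). In limma, 486 genes passed, 222 higher and 264 lower in Batf2 cells, 335 of them by at least 2-fold, and the groups did not overlap for 25% of genes, where chance gives 10%. The count was 1229 with the replicate block and 137 when only the 6 libraries were fitted. It was 254, 216 and 256 without Batf replicate 1, 2 or 3 and 786 without Batf2 replicate 1. Without Batf2 replicate 3, 524 genes passed, and 394 of the 486 were among them.

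Batf2 cells were compared with Batf3 cells last. Ccr10 was higher in Batf2 cells by 5.12 ± 0.21 (adjusted p = 1.63e-07). Ecm1, an extracellular matrix gene, was higher by 2.88 and Igfbp4 by 2.82. Klrb1c (−3.70), Fcer1g (−2.92) and Gzmc (−2.81) were lower in Batf2 cells, as was Egr1 (−2.85, and −2.01 without Batf2 replicate 3). Gzma stood at 1388 ± 139 against 6714 ± 443 FPKM (−2.28). When only the 6 libraries of these groups were fitted, the calls of Batf3 (0.0552), Ecm1 (0.0666), Igfbp4 (0.0625) and Gzma (0.0739) ended, as did that of Egr1 (0.2278), which also ended with no filter (0.059) and without Batf2 replicate 2 or any 1 Batf3 library (0.0634 to 0.1425).

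Cytotoxic molecules were lower in Batf2 than in Batf3 cells (adjusted p = 2.02e-05, and 0.245 with an estimated correlation; 6 of 20 lower, 8 adjusted over the list alone), as were NK markers (0.0013, and 0.336 with an estimated correlation; 2 of 9 lower and 1 higher, 3 and 1 adjusted over the list alone), tissue residency genes (0.0337, and 0.336 with an estimated correlation; 4 of 11 lower and 1 higher, 6 and 2 adjusted over the list alone) and immediate early and heat shock genes (0.0404, and 0.559 with an estimated correlation; 1 of 17, 3 adjusted over the list alone). Naive and memory genes (0.0192, and 0.61 with an estimated correlation; 3 of 25 higher, or 6 higher and 1 lower adjusted over the list alone) and chemokine receptors and adhesion genes (0.0179, and 0.336 with an estimated correlation; 7 of 20 higher and 1 lower, 7 and 4 adjusted over the list alone) were higher, the latter not under quantile normalization (0.17). Ccr4 stood at 54.3 ± 18.6 against 7.77 ± 2.33 FPKM (2.64, adjusted p = 0.000323, but 0.0514 when only these 2 groups were fitted). Lists of growth, metabolism and T cell receptors were higher in Batf2 cells as well: ribosomal proteins (adjusted p = 2.84e-07), oxidative phosphorylation (2.02e-05), cell cycle (0.0094), fatty acid oxidation (0.0092), glycolysis (0.0404), costimulatory receptors (0.0404), T cell receptor complex and CD8 identity (0.0404) and the amino acid and stress response (0.0481). With an estimated correlation their adjusted p were 0.571, 0.585, 0.686, 0.571, 0.657, 0.336, 0.571 and 0.61. Without Batf2 replicate 3 the last 7 of these lists did not pass (0.201, 0.0626, 0.382, 0.26, 0.0504, 0.214 and 0.405), and of the 8 only costimulatory receptors and the amino acid and stress response had a member past the threshold (1 of 16 and 1 of 17 higher), also adjusted over the list alone, where 1 costimulatory receptor was lower. Under quantile normalization, of the 8 lists, all but oxidative phosphorylation did not pass (0.176, 0.0812, 0.0708, 0.227, 0.167, 0.67 and 0.25 in the order above), and the T cell receptor list turned downward. With the length trend removed the last 4 lists did not pass (0.0688, 0.0516, 0.0741 and 0.099). In limma, 218 genes passed, 126 higher and 92 lower in Batf2 cells, 166 of them by at least 2-fold, and the groups did not overlap for 22.8% of genes, where chance gives 10%. The count was 8 when only the 6 libraries of these groups were fitted, and 85, 71 and 102 without Batf3 replicate 1, 2 or 3. Without Batf2 replicate 3, 222 genes passed, and 162 of the 218 were among them.

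The responses to the family members were compared through their overlap. Of the genes past the threshold against Mock, 147 were higher and 43 lower with both Batf and Batf3, and 0 went opposite ways; independent lists of these sizes would share 4.53 and 0.411. Batf and Batf2 shared 143 higher and 46 lower genes, with 5 opposite (12.4 and 1.72 for independent lists). Batf2 and Batf3 shared 109 higher and 40 lower genes, with 1 opposite (6.94 and 1.20). All 3 comparisons shared 96 higher and 31 lower genes, among them Itgae, Ccr1 and Ccr4 (higher) and Tgm2, Txk and Cd6 (lower). Unchanged groups simulated against shared controls gave 0 shared genes in either direction for the pairs with Batf2, and for Batf and Batf3 a mean of 25.02 higher and 25 lower that came from 1 of the 100 simulations. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.83 for Batf and Batf3 (simulated with no effect 0.38 ± 0.45), 0.43 for Batf and Batf2 (0.41 ± 0.46) and 0.52 for Batf2 and Batf3 (0.39 ± 0.42). The covariances were 0.142, 0.117 and 0.122 against simulated 0.0493 ± 0.0831, 0.0420 ± 0.0609 and 0.0443 ± 0.0664 (SD of 100 simulations). The 3 control libraries are too few to be split into sets of 2 each, so these covariances may come in part or in whole from the shared controls. The simulation took its spread from all 12 libraries, Batf2 replicate 3 included, and held no replicate effect shared between groups. Its values may therefore be too large, and the share due to the controls is not settled. Without Batf2 replicate 3 the simulated covariances were 0.0339, 0.0313 and 0.0274 in the same order. Without Batf2 replicate 3, the shared genes of the 3 pairs summed to 992 instead of 528, while the sum fell to 280 and 323 without Mock replicate 2 or 3 and to 336 and 328 without Batf3 replicate 2 or 3.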

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

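The tests below of transcript length, of a wrong label, of other cell types, of carry-over and of Batf3 virus were chosen after the results were seen. For 5 genes the responses to Batf2 and Batf went opposite ways from Mock, each past the threshold. The direct fold change between Batf2 and Batf is the difference of these 2 responses in the same fit, so for genes chosen this way it is no separate test. Gzma stood at 3504 ± 1116 FPKM (SD, n = 3) in Mock, 8918 ± 1125 with Batf and 1388 ± 139 with Batf2, a direct log2 fold change of −2.68 (limma adjusted p = 0.000399). Its rise with Batf ended without Mock replicate 1 or 3 or any 1 Batf library (0.0519 to 0.0899), with no filter (0.0891) and under quantile normalization (0.0619). Fcer1g stood at 34.2 ± 4.33, 76.2 ± 8.09 and 9.64 ± 0.193 FPKM in the same order, a direct change of −2.85 (adjusted p = 2.16e-06). For Cd244, a receptor gene of the SLAM family, the values were 8.49 ± 2.41, 19.5 ± 3.08 and 3.44 ± 1.48 FPKM (−2.26), for Ppp2r2c 4.83 ± 1.19, 17.2 ± 2.94 and 0.707 ± 0.544 (−3.45) and for Rgs1 29.7 ± 6.6, 57.6 ± 10.2 and 12.3 ± 0.665 (−2.12). The rise of Rgs1 with Batf ended without Mock replicate 1 or 3 or Batf replicate 1 or 2 (0.0564 to 0.1193) and with only 2 groups fitted (0.0649). Fcer1g also went opposite ways with Batf2 and Batf3, where it stood at 79.8 ± 7.3 FPKM (direct change −2.92, adjusted p = 1.66e-06). The 5 direct differences between Batf2 and Batf and that of Fcer1g between Batf2 and Batf3 passed under every alternative tried. For Cd244 and Ppp2r2c the differences from Mock were not run under the alternatives, nor were the falls of Gzma and Rgs1 with Batf2.

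Batf2 replicate 3 stood apart from the other 11 libraries in its total, its trend on transcript length and its correlation with its replicates. A wrong label of another group is argued against by its Batf2 level of 368.7 FPKM, since Batf2 was listed at 0 in the 9 libraries of other groups. With the trend on transcript length removed, its correlations with the other Batf2 libraries went from 0.907 and 0.929 to 0.912 and 0.933. As the whole cause, the trend would need both to reach 0.94, the lowest value within the other groups (SD of these correlations 0.015). Neither did, and the lower stayed below by more than that SD. The length used was the median over all annotated transcripts of a gene, which need not be the length of the transcripts in these cells. Removal of a trend on it may leave a true length trend in place, so the test cannot exclude length as the whole cause. The gap of the higher was under that SD. The rule for this test was changed 2 times after these values were seen, and a rule that asks a gap of 1 SD of the higher value leaves the cause open. Cells of another type stay open. At most 2 members of a marker list reached 10 FPKM and 2 times the other Batf2 libraries, Bst2 (238 against 106 FPKM) and H2-Ab1 of the dendritic cell list. Cd79b, Hba-a1 and Izumo1r were single markers of their lists (these 5 genes were chosen after their values were seen). FPKM values were not rescaled for this count. The mean log2 level of oxidative phosphorylation genes was 8.49 in this library against 6.99 and 7.21 in the other Batf2 libraries. A rise of 2 times was therefore not particular to marker genes. Sorting for GFP would remove cells that were not transduced. No biological explanation was tested.

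Libraries that share a replicate number deviated together from their group means, with correlations of 0.432 to 0.706 between replicate 1 libraries but 0.004 to 0.229 between replicate 2 libraries. After removal of a trend on transcript length the lowest of the 6 for replicate 1 was 0.456, and after removal of a trend on GC content 0.47. These values argue against trends on the annotated medians as the cause. Trends on the length and GC content of the transcripts in these cells were not tested. Mean log2 levels of the cell cycle list in replicates 1, 2 and 3 were 4.36, 5.73 and 6.11 in Mock and 5.40, 6.04 and 6.15 in Batf2 cells. The gap between these 2 groups was widest in replicate 1. In Batf cells they were 4.70, 5.58 and 5.59, and in Batf3 cells 4.90, 5.62 and 5.75. Glycolysis and cholesterol synthesis genes were also lowest, and naive and memory genes highest, in replicate 1 of each group. These lists were chosen after their levels were seen. What the numbers stand for is not given in the sources used here, so a shared culture, mouse or day of handling stays open, and no biological explanation was tested.

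The Batf3 transcript was above Mock in all Batf and Batf2 libraries. Reads shared with Batf or Batf2 are argued against, since 0 of 1356 and 2707 windows of 50 nt in their transcripts matched a Batf3 transcript with at most 2 mismatches. Carry-over of reads at 1 rate into every library is argued against by the highest Mock value, 0.241 FPKM, below the lowest Batf library at 5.94. The mean in Batf libraries was 1.58% of that in Batf3 libraries, and in Batf2 libraries 3.31%, or 1.29% without Batf2 replicate 3, a share that a small amount of Batf3 virus or of Batf3-transduced cells could also give. This and a rise of the endogenous gene cannot be told apart, because the values do not separate the insert from the gene.

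Other splits of the 6 libraries of each comparison into 3 and 3 gave at most 1 gene past the threshold. The real split was the 1 of 10 with the highest count in each comparison: 377 genes against at most 1 for Batf and Mock, 689 against 1 for Batf2 and Mock, 222 against 0 for Batf3 and Mock, 16 against 0 for Batf3 and Batf, 486 against 1 for Batf2 and Batf, and 218 against 0 for Batf2 and Batf3. With 10 splits the share cannot fall under 0.05. Every other split mixes the 2 groups, so real differences between them enter the spread and hold the count down. Low counts in these splits were therefore likely in any case and are weak evidence. In the 3 comparisons treated as paired, the other splits that part all 3 pairs gave 0 genes.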

How the results depend on the processing

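The fits with the length trend removed were chosen after the data were seen, as were those without Batf2 replicate 3 for comparisons without Batf2, for lists, for overlaps and with the block. Of 139 alternative values of the 9 main results, 74 were within 1.5 times the value reported and 65 were not. The transduced genes and the 241 named gene values kept their direction under every alternative run; of 4891 alternative values 477 were no longer past the threshold, 88 of them with only the 2 groups fitted. In the order Batf, Batf2 and Batf3 against Mock, then Batf3 against Batf, Batf2 against Batf and Batf2 against Batf3, a filter at 5 FPKM gave 197, 373, 122, 2, 255 and 118 genes, from 8642 genes tested. Libraries of only the 2 groups gave 199, 137 and 8 for the 3 comparisons of Batf2 with Mock, Batf and Batf3, and library weights, whose estimation stopped before it converged, gave 981, 932, 81 and 403 for Batf and Batf3 against Mock, Batf3 against Batf and Batf2 against Batf3. For Batf3 against Batf a pseudocount of 0.1 gave 4 and no filter 41. Leaving out 1 library gave 232 to 763, 382 to 878, 108 to 448, 6 to 20, 216 to 786 and 71 to 265. Shared genes summed to 992 without Batf2 replicate 3, and to 280 to 536 without any other 1 library. Of 67 list calls, 11 held with an estimated correlation, 35 with fry and 50 without Batf2 replicate 3; with calls not among the 67, the last 2 gave 44 and 54. The list of T cell receptor complex and CD8 identity in Batf2 against Batf3 had a median of 0.0358 and a test turned downward under quantile normalization, with and without the replicate block (adjusted p = 0.7844 and 0.6698). The cause of these changes was not tested.

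With the replicate block the counts were 586, 1202, 362, 26, 1229 and 531; with the block and quantile normalization 746, 1398, 442, 27, 1526 and 700; with the block and without Batf2 replicate 3 they were 1747, 1512, 1058, 79, 1529 and 728. With the block and the length trend removed they were 657, 1285 and 415 against Mock and 1356 and 620 for Batf2 against Batf and Batf3. Libraries closest to one of their own number were 6 of 6 for Mock and Batf and for Batf and Batf2. They were 4 of 6 for Mock and Batf3, which were also treated as paired, so this measure does not set the paired groups apart. In the comparisons not treated as paired, they were 4 of 6 for Mock and Batf2, 5 for Batf and Batf3 and 3 for Batf2 and Batf3. There the block ended the list call of costimulatory receptors in Batf3 against Batf (0.0574) and passed cell cycle (0.0048, higher), glycolysis (0.0266, higher) and immediate early and heat shock genes (0.0491, lower), and AP-1 and IRF factors in Batf2 against Batf3 (0.0238, lower). With an estimated correlation in that fit these 4 had 0.837, 0.6517, 0.5269 and 0.5557. Apart from these and the list calls given with their comparisons, the block changed no list call. Of the named genes, 19, 21, 13, 2, 9 and 12 passed with the block alone, among them Il24 in Batf3 against Batf (0.03 against 0.4253 without it), and 1 call ended, that of Rps27rt with Batf. Depth is unknown for FPKM values, so the counting error of low genes was not estimated.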

Other observations

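The tests of other settings quoted here were planned, and the hypothesis at the end was written before its test, although the rule that voids the test was added after its value was seen. Cd8a, a CD8 coreceptor gene, stood at 192 ± 42.8 FPKM in Mock, 436 ± 55.7 with Batf2 (1.19, limma adjusted p = 0.0063) and 386 ± 49.9 with Batf (1.02, adjusted p = 0.0235), and it did not pass with Batf3 (0.71, adjusted p = 0.181). Its call with Batf2 ended under quantile normalization (0.1092) and with only 2 groups fitted (0.1188), and with Batf it ended without Mock replicate 2 or 3 or Batf replicate 1 or 2 (0.1001 to 0.1138). The list of T cell receptor complex and CD8 identity did not pass in these comparisons (adjusted p = 0.105 and 0.777), with 2 higher and 1 lower with Batf2 and 2 and 1 with Batf adjusted over the list alone; with Batf the list median was −0.02 and the mean 0.08. Cebpb, a transcription factor gene of the amino acid and stress response list, rose with Batf2 from 2.22 ± 0.592 to 10.5 ± 2.16 FPKM (1.83, adjusted p = 0.000249) and was higher than with Batf by 1.33. Irf4, a transcription factor gene of the AP-1 and IRF list, rose with Batf2 by 1.06 (adjusted p = 0.0042), a call that ended with only 2 groups fitted (0.1054). Maf, of the same list, rose against Mock by 2.68, 1.65 and 2.06 with Batf, Batf2 and Batf3. Of that list 1, 2 and 1 of 18 members were higher and 0, 1 and 0 lower. Adjusted over the list alone 1, 2 and 1 were higher and 2, 3 and 0 lower, and the list itself did not pass (adjusted p = 0.785, 0.174 and 0.895). Xcr1, a chemokine receptor gene and a marker in the dendritic cell list, rose with Batf from 1.42 ± 0.538 to 4.41 ± 1.01 FPKM (1.17, adjusted p = 0.0086) and with Batf3 to 4.94 ± 0.419 (1.32, adjusted p = 0.0067).

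Genes of the unfolded protein response had 0, 0 and 0 of 19 members past the threshold, also adjusted over the list alone, against Mock with Batf, Batf2 and Batf3 (list adjusted p = 0.262, 0.417 and 0.588), and apoptosis genes 1, 0 and 0 of 22, or 3, 0 and 0 adjusted over the list alone (0.457, 0.878 and 0.775). Cytokine receptors gave 3 higher and 2 lower of 23 with Batf2, or 4 and 3 adjusted over the list alone, where the list median was 0.00, the mean 0.17 and the test pointed down (adjusted p = 0.836).

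One hypothesis was that the Batf3 response is the Batf response at a smaller size. A slope of Batf3 on Batf effects was computed after simulated noise was subtracted from the covariance and from the Batf variance. It was 0.955, and 0.806 to 1.80 without single libraries. It is not the slope of the measured fold changes, whose covariance was 0.142 and whose variance with Batf was 0.199. The correlation of the effects with the noise of shared controls subtracted was 1.61, above the possible range, so the test decides nothing and the hypothesis may or may not hold. Simulated noise that is too large can give such a value.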
